A study of Mus musculus with 2 samples.

How the data were processed

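H3K4me1 ChIP-seq was carried out on pooled whole hearts of mixed-sex mouse embryos at embryonic day 16.5, in 2 biological replicates with 2 technical replicates each and a library size range of 300 to 500, per the labels. The authors deposited 4 peak lists in narrowPeak format on mm10. Per the records deposited with the files, replicate 1's list was made from its alignment and 2 further input files, replicate 2's list from its alignment and 1 further input file, and the replicated list from the pooled list and both replicates' lists. The aligner, the peak caller, their versions, the control used for each list and the rule for a replicated peak are not given in the sources used here. The fold enrichment of each peak was used as deposited, as a linear ratio to a background that the sources used here do not define. The −log10 p and −log10 q values of each peak were also taken as the authors deposited them, and the lists reach down to a −log10 q of 0.323 in replicate 2 and 0.674 in replicate 1, so many peaks are weak. A −log10 q of at least 2 was reached by 85.5% of replicate 1's peaks, 39.0% of replicate 2's and 84.9% of the replicated list. These values served only to describe, rank or filter peaks within a list. Depth is unknown, so no value carries an interval for read sampling, and intervals over peaks, windows or genes describe these lists only, since neighbouring peaks are not independent.

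Positions were read against the GRCm38 assembly, which is the mm10 build, and GENCODE M21 gene models (Ensembl 96). No peak ran past a chromosome's end. The 19 autosomes, X and Y were used, and 1 peak on another contig was left out of each list but replicate 2's. Peaks of a list did not overlap each other. The replicated list was the main one, each replicate's own list gave the mean ± SD (n = 2), and all counts of bases refer to the assembled sequence without N. The pools came from separate biological samples by the labels, but with 2 replicates no test between replicates can reach a useful p, so differences are set against their spread.

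Replicate overlap was the share of peaks covered over at least 50% of their length by the other list, set against 100 random placements of the other list on the same chromosomes. Summits were classed in the order promoter (within 1000 bp of any annotated transcript start), exon, intron and intergenic. Coverage around start sites used the most 5' start of each of 21938 protein-coding genes at 100 bp steps to 10 kb either side, and a promoter was called CpG-rich at an observed/expected CpG ratio of at least 0.6 over 500 bp either side. The flank was the highest share within 3 kb. Gene lists were tested on the median percent of TSS ± 50 kb covered by peaks against 10000 random lists of protein-coding genes matched on the number of other protein-coding start sites in the window, with a two-sided permutation p, Benjamini-Hochberg adjustment over 17 lists and a threshold of 0.05. All genes of the lists were found in the annotation. Genes are not replicates, so these tests describe these hearts' peak lists. Motifs were fixed consensus sequences searched on both strands of 400 bp windows, and control windows were matched on chromosome, on GC in steps of 2 percentage points and on being mostly repeat-masked. Domains were replicated peaks joined across gaps of up to 5 kb and ranked by covered length.

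The lists, motifs, thresholds, most alternatives and the rule for naming genes were set before the data were examined. The rule named, of each list, the 2 genes with the highest and the 1 with the lowest covered percent, the 20 most covered protein-coding genes with start sites over 100 kb apart, the genes nearest to the 10 peaks of highest fold enrichment with 1 peak kept per gene, the genes at the 10 largest domains, and 17 genes of the heart and of other tissues in every case. Genes lying at such a peak or domain, or beside a named gene, were named after their values were seen, which applies to Ndst1, Camk2b, Pex14 and Gse1. Alternatives were the pooled list, each replicate's list alone, a stricter q, the stronger part of the peaks, other windows, other promoter widths, other control sequences and other gaps. Chosen after seeing the data were the replicated peaks that touched both replicates' own peaks, flanking motif windows matched on GC and repeats, 20 scrambled orders of the MEF2, GATA, TEAD and NKX2-5 consensuses, the test of the X copy number with the lowering of every fold, and the olfactory and vomeronasal receptor families.

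The code was tested on simulated data first. Interval counts matched a base-by-base count in 500 of 500 windows, and the motif search recovered 800 of 800 planted MEF2 windows with 0 of 14 unplanted motifs called. In the gene list test, 200 simulated lists of 20 genes with no change gave a p under 0.05 in 7.5% of cases, lists raised by a factor of 2 in 53.5% and by a factor of 3 in 79.0%, before adjustment, so lists with smaller gains may be missed. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.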

Results

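Monomethylation of lysine 4 on histone H3 (H3K4me1), a mark carried by enhancers and by the flanks of active promoters, was mapped by ChIP-seq in whole mouse hearts at embryonic day 16.5. The series held 1 group of 2 biological replicates, each a pool of hearts from male and female embryos of the B6NCrl strain. Replicate 2 pooled the hearts of 41 embryos, and the label of replicate 1 gave no number. Each replicate joined 2 technical replicates. The data were 4 peak lists on the mm10 build: replicate 1's own list, replicate 2's own list, a list called on both replicates pooled, and a replicated list drawn from the pooled list with the help of the replicates' lists. No read counts were given, so the sequencing depth of each sample is unknown, and no second tissue, stage or condition was measured. The comparisons were therefore between the replicates, between the mark and the genome, and between sets of genes within these hearts.

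H3K4me1 peaks covered 79.0 Mb, or 2.98% of the assembled genome, in the replicated list of 141170 peaks. Replicate 1 gave 228627 peaks over 103.8 Mb and replicate 2 gave 112269 peaks over 42.7 Mb. The pooled list had 175577 peaks over 86.9 Mb. Peaks were narrow in every list, with median widths of 312 bp in replicate 1, 292 bp in replicate 2, 341 bp in the pooled list and 403 bp in the replicated list. Most of replicate 2 lay within replicate 1: 83.7% of its peaks were overlapped over at least 50% of their length by replicate 1 (95% Wilson interval 83.5 to 83.9%), against a mean of 3.99% and a highest value of 4.15% over 100 random placements. In the other direction, 24.7% of replicate 1's peaks were overlapped by replicate 2 (24.5 to 24.9%), against a random mean of 1.54% and a highest value of 1.596%. The overlapped share of replicate 1 was 10.2% in the 10% of its peaks with the lowest fold enrichment and 65.2% in the 10% with the highest. The corresponding shares of replicate 2 were 75.6% and 98.4%. Of the replicated peaks, 96.2% shared at least 1 bp with a peak of replicate 1, 60.03% with a peak of replicate 2, and 58.0% with peaks of both, so membership of the replicated list did not require a peak in each replicate's own list. These shares depended on the overlap and the threshold chosen: with an overlap of 1 bp 38.5% of replicate 1's peaks were overlapped, with the same number of peaks per replicate 38.0%, and with a −log10 q of at least 2 in both lists 12.7%. When 50% of both peaks had to be covered, the share of replicate 2 was 37.5%.

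**Figure D1:**
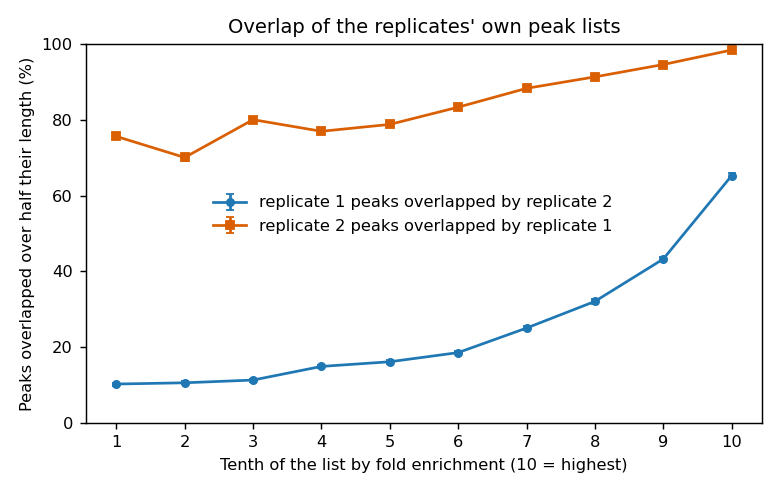
Share of each replicate's own peaks overlapped over at least 50% of their length by the other replicate (vertical axis, percent), with the list split into 10 equal parts by fold enrichment (horizontal axis, 10 the highest). Bars are 95% Wilson intervals over peaks and are mostly smaller than the points. The share for replicate 1 (blue circles) rose from 10.2% to 65.2%, and that for replicate 2 (orange squares) was 75.6% in the lowest part and 98.4% in the highest.

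The mark lay mostly inside genes and away from their start sites. Introns held 54.5% of the replicated summits, against 38.3% of the genome, and the mean over the replicates' own lists was 55.8% ± 1.21 (SD, n = 2). Regions within 1000 bp of an annotated transcription start site (TSS) held 18.9%, which was 3.12 times their 6.05% share of the genome, with a mean of 17.6% ± 1.34 (SD, n = 2). Exons held 4.57% against 3.18% of the genome. Intergenic sequence was depleted, with 22.01% of the summits against 52.4% of the genome, a ratio of 0.420, and a mean of 22.1% ± 2.53 (SD, n = 2). Each of these departures from the genome's shares was larger than the spread between the replicates. The median summit was 6.54 kb from the nearest TSS, 71.3% of summits were more than 2 kb away and 7.29% more than 50 kb. Within the replicated list the promoter share was 17.4% in the lowest 10% of peaks by fold enrichment and 22.9% in the highest, while the intergenic share was 23.4% and 15.1% and the median width 320 bp and 968 bp. The promoter share depended on the promoter's definition, at 9.90% for 500 bp and 32.1% for 2500 bp either side of the TSS.

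Around the start sites of CpG-rich promoters, the class used by most broadly expressed genes, the mark formed a pair of shoulders with a gap between them. Of 10081 such protein-coding start sites, 4.67% were covered by a replicated peak at the TSS itself, 43.9% at 1100 bp downstream and at most 28.5% on the upstream side. The covered share at the TSS was thus 0.106 of that at the highest flank, with a mean over the replicates' own lists of 0.101 ± 0.0484 (SD, n = 2; 0.135 in replicate 1 and 0.0668 in replicate 2). A peak lay within 3 kb of 92.0% of these sites. The 11857 CpG-poor start sites showed a far shallower dip, with 9.29% covered at the TSS and 11.9% at 300 bp upstream, a ratio of 0.782 with a mean of 0.772 ± 0.0795 (SD, n = 2). A peak lay within 3 kb of 37.6% of them. The gap between the ratios of the promoter classes exceeded the spread between the replicates.

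**Figure D2:**
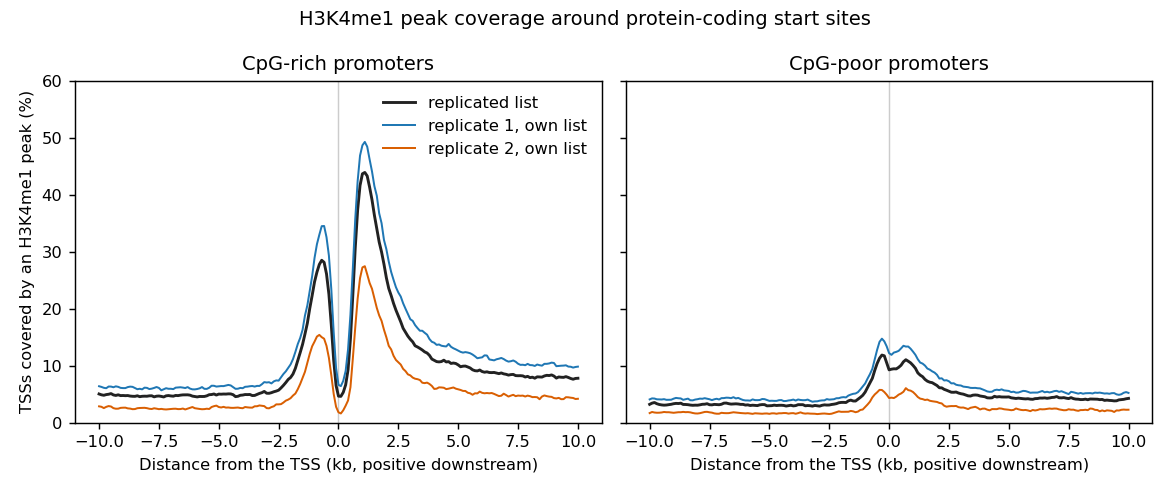
Percent of protein-coding start sites covered by an H3K4me1 peak (vertical axis) against the distance from the TSS in kb, positive downstream (horizontal axis), for 10081 CpG-rich promoters on the left and 11857 CpG-poor promoters on the right. The black line is the replicated list, blue replicate 1 and orange replicate 2. In the replicated list, coverage of CpG-rich sites fell to 4.67% at the TSS between shoulders of 28.5% upstream and 43.9% downstream.

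Genes of the heart muscle and of heart development were surrounded by more peak coverage than random genes of the same local gene density. The random genes were not matched on expression or gene length. Any part of the excess that expressed genes of other kinds would share was therefore not separated, and housekeeping genes also passed. For each of 17 gene lists, the percent of TSS ± 50 kb covered by peaks was compared with 10000 random lists of the same size and local gene density by a two-sided permutation test, with Benjamini-Hochberg adjustment over the lists. Cardiac transcription factors had a median of 10.2%, 4.90 times the median of the random lists, cardiac contractile genes 16.1% (4.62 times), calcium handling and conduction genes 9.66% (4.07 times) and heart developmental signalling genes 9.98% (4.05 times). All 4 had a permutation p of 0.0002, the smallest that 10000 random lists can give, and an adjusted p of 0.0008. Random genes were drawn independently, whereas some lists hold neighbours with shared windows, such as Tnni1 and Tnnt2, so p values of such lists may be too small. Their calls held under every alternative, but the ratios depended on the setting: 2.92 to 5.73 for transcription factors (lowest with unmatched random lists), 2.90 to 6.78 for contractile genes (lowest with TSS ± 100 kb), 2.81 to 4.82 for calcium handling and 2.81 to 5.44 for signalling. With random genes also matched on promoter CpG class, transcription factors stood at 3.53 and contractile genes at 6.78, so the order of these lists was not fixed. Energy metabolism and natriuretic peptide genes had 9.07% (2.89 times, adjusted permutation p = 0.0054) and housekeeping genes 9.35% (2.16 times, adjusted permutation p = 0.0266). In the replicates' own lists the ratio was 4.36 and 5.09 for transcription factors, 3.89 and 4.14 for contractile genes, 3.65 and 3.88 for calcium handling, 3.25 and 3.94 for signalling, 2.67 and 2.499 for metabolism, and 2.01 and 2.18 for housekeeping genes, replicate 1 first. The metabolism call was lost in replicate 2's list alone (adjusted permutation p = 0.0561) and with TSS ± 100 kb (0.0827), and ranged over its alternatives from 0.0007 to 0.0827. The housekeeping call was lost when random genes were also matched on promoter CpG class (ratio 1.62, adjusted permutation p = 0.0767) and with the replicated peaks that touched both replicates' own peaks (0.0510), over a range from 0.0027.

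Among the 26 cardiac transcription factors, 23 lay above the median of all 21938 protein-coding genes, which was 3.46%. The highest were Tead1, a partner of the Hippo pathway's coactivators, at 35.7% (mean of the replicates' own lists 31.8% ± 15.7, SD, n = 2; TSS at chromosome 7, position 112679318) and Gata4, a zinc finger factor needed for heart formation, at 30.1% (24.1% ± 15.6; chromosome 14, position 63271692). Nkx2-5, an early marker of cardiac fate, had 17.6% (16.6% ± 7.09; chromosome 17, position 26845009), Hand2 11.4% and Tbx5 11.4%. The lowest was Isl1, a factor of cardiac progenitors, at 0.549% with 1 peak in its window. The SDs were wide because replicate 2's list covered less throughout. Across genes, which are not independent replicates, the covered percents of the replicates had a Spearman correlation of 0.967.

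Of the 25 contractile genes, 23 were above the median gene. Tnni1, the slow troponin I of fetal heart, had 37.9% (29.5% ± 14.6, SD, n = 2), Tcap, which caps titin at the Z-disc, 33.9% (30.0% ± 14.4) and the cardiac troponin T gene Tnnt2 32.8% (24.8% ± 14.01). Tnni1 and Tnnt2 are neighbours on chromosome 1, with start sites at 135779434 and 135836354, so their windows shared peaks. The myosin heavy chain genes Myh6 and Myh7, also neighbours, had 16.3% and 13.9%. Titin itself, Ttn, had 5.62%, and the lowest was the nebulette gene Nebl at 2.15%. In the calcium handling list 15 of 23 genes were above the median gene, led by Jph2, which ties the cell membrane to the calcium store, at 34.9% (29.7% ± 11.02) and the calcium release channel Ryr2 at 30.1% (25.8% ± 12.5), with the potassium channel Kcnd2 lowest at 0.294%. The metabolism list had 18 of 20 above the median gene, with the myoglobin gene Mb at 24.7%, Pdk2 at 23.3%, the natriuretic peptide genes Nppb and Nppa at 9.80% and 8.41%, and Pdk4 lowest at 2.57%. Of the 23 signalling genes 15 were above it, led by the inhibitory SMAD genes Smad7 at 36.8% (32.0% ± 8.88) and Smad6 at 35.6% (29.1% ± 13.1), with Alk lowest at 0.992%. The housekeeping list had 17 of 22 above the median gene, with Rplp0 at 24.6%, Ywhaz at 21.6% and the X-linked Hprt lowest at 0.748%.

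Lists for the other cell types of the heart did not pass the test. This does not show a lack of excess, since simulated lists of 20 genes raised by a factor of 2 reached a p under 0.05 in only 53.5% of cases. Endothelial and endocardial genes had a median of 6.06%, 2.14 times the random median, with an adjusted permutation p of 0.0792, and 17 of 24 lay above the median gene. This list passed under 4 alternatives, with adjusted permutation p values between 0.0091 and 0.5163 over all of them: replicate 1's list alone, TSS ± 20 kb, the gene body with 5 kb either side, and the number of peaks in place of their length. Notch1 had 31.9% and Eng 26.3%, while Cdh5, a junction protein of all endothelium, had 1.21% and the ETS factor Erg 0.431%. Smooth muscle and pericyte genes had 6.65% (2.07 times, adjusted permutation p = 0.206), with 10 of 13 above the median gene, Cspg4 at 22.5%, Smtn at 14.8% and Rgs5 at 0.683%. Fibroblast and valve mesenchyme genes had 2.77% (1.22 times, 0.835), with 9 of 19 above the median gene, Thy1 at 14.3%, Meox1 at 12.4% and no replicated peak in the window of Col3a1. Epicardial genes had 2.67% (0.886 times, 0.888), with 5 of 12 above the median gene, Upk3b at 9.30%, Msln at 9.06%, Wt1 at 4.59%, Tcf21 at 2.97% and Sema3d at 0.312%.

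No list for blood cells or other organs passed the test. The ratio to the random median was 0.682 for erythroid genes (adjusted permutation p = 0.781), 0.623 for macrophage and leukocyte genes (0.774), 0.850 for hepatocyte genes (0.835), 0.835 for neural genes (0.835), 0.953 for skeletal muscle genes (0.893), 0.839 for lung epithelial genes (0.835) and 0.833 for germline and pluripotency genes (0.835). The side of 1 on which these ratios lay depended on the setting. With random genes also matched on promoter CpG class they were 1.16 for erythroid, 1.37 for macrophage and leukocyte, 1.84 for hepatocyte and 1.62 for skeletal muscle genes, and over the gene body with 5 kb either side 0.184 for erythroid, 0.143 for hepatocyte and 0 for germline genes. None of these lists passed the test under any alternative. The numbers of genes above the median gene were 6 of 12, 7 of 15, 11 of 24, 11 of 25, 13 of 24, 5 of 15 and 8 of 19 in the same order. No replicated peak lay in the windows of Alb, Cps1, Hbb-bt, C1qa, Slc17a6, Myh2, Lamp3 or Sycp1. Some other genes of these lists, not picked by the naming rule, had none either. The same held for 19.4% of all protein-coding genes, so an empty window does not set these genes apart. Neurod1, a neuronal and endocrine factor, had 0.798%, and Myod1, a determinant of skeletal muscle, 0.523%. The highest in each list were Nfe2 (18.3%) and Epor (8.80%), Spi1 (14.2%) and Cd68 (11.02%), Apoa2 (16.7%) and Apoh (10.3%), Neurod2 (19.8%) and Eomes (11.3%), Tnnt3 (35.0%) and Tnni2 (23.6%), Sftpb (13.1%) and Scgb1a1 (12.7%), and Spo11 (19.7%) and Prm1 (15.1%). A window of ± 50 kb also holds a gene's neighbours: the start site of Neurod2 at 98329648 on chromosome 11 lies beside that of Tcap at 98383811, so these values cannot be assigned to the named gene alone.

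**Figure D3:**
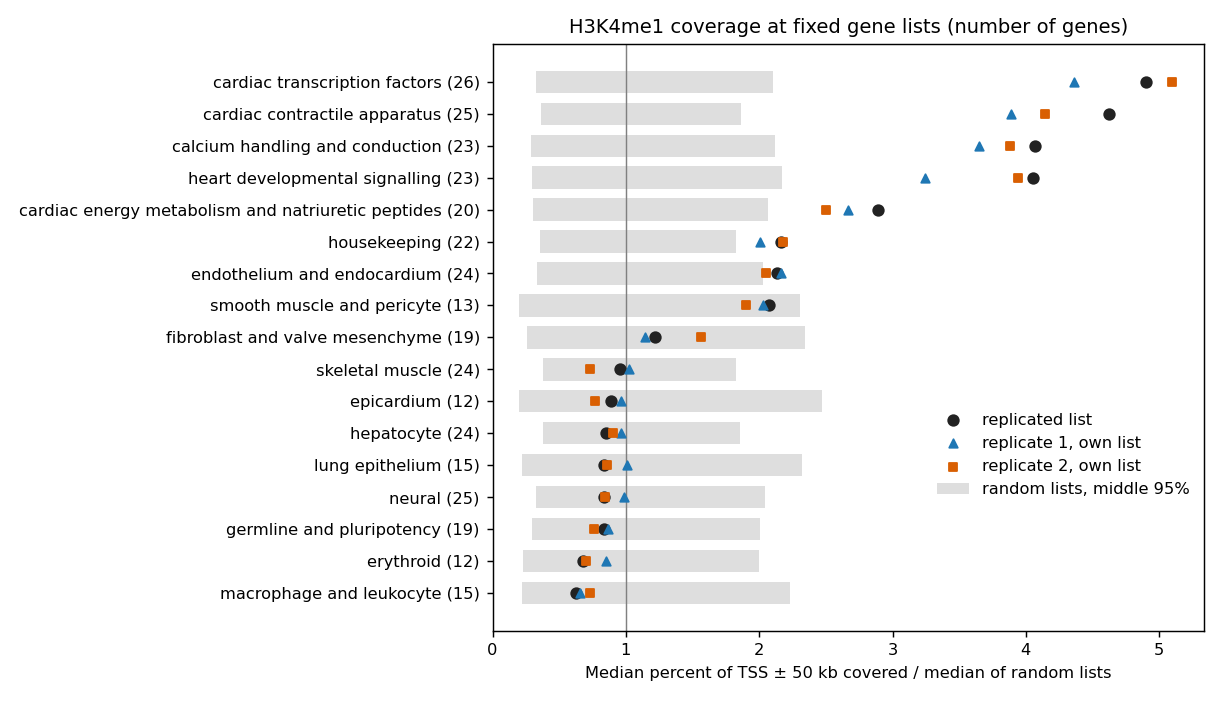
Median percent of TSS ± 50 kb covered by peaks for each of 17 gene lists, divided by the median of random lists matched on gene density (horizontal axis), with the number of genes in brackets. Black circles are the replicated list, blue triangles replicate 1 and orange squares replicate 2, and grey bars span the middle 95% of the random lists for the replicated list. The transcription factor, contractile, calcium handling and signalling lists lie at ratios of 4.90, 4.62, 4.07 and 4.05, to the right of their bars.

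None of the 20 most covered genes with start sites over 100 kb apart was in a fixed list. Igf2r, the receptor that clears insulin-like growth factor 2, had 52.7% of its window covered (46.4% ± 13.1, SD, n = 2; gene at chromosome 17, 12682406 to 12769664), and Zmiz1, a transcriptional coactivator, 51.0% (44.5% ± 11.8; chromosome 14, 25459185 to 25666743). They were followed by Mical2, an actin oxidising enzyme, at 49.1% (41.8% ± 11.03), the collagen IV gene Col4a1 at 47.0% (42.4% ± 18.4) and the retinoic acid receptor gene Rara at 45.9% (41.2% ± 9.47). Ahdc1, Ski, Ncor2, Rcsd1, the thyroid hormone receptor gene Thra, Ifrd2, Actn4 and Mapkapk2 lay between 44.9% and 40.2%. Myh9, Trim8, Map4k4, Phlda3, Sh3pxd2a, Bahcc1 and Stk24 lay between 39.8% and 39.0%. Phlda3, with its start site at 135766119 on chromosome 1, is a neighbour of Tnni1.

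The replicated peak of highest fold enrichment lay in an intron of Rara (chromosome 11, 98942052 to 98946441), with a fold enrichment of 12.1 as the authors' peak caller gave it. The next were in introns of Ndst1 (chromosome 18, 60734254 to 60737338, fold 11.7, nearest start site Rps14), Anxa6 (chromosome 11, 55020069 to 55023281, fold 11.5), Ptp4a3 (chromosome 15, 73728884 to 73734598, fold 11.4) and Pkig (chromosome 2, 163673732 to 163675613, fold 11.02). A peak with a fold of 10.96 at chromosome 11, 6000780 to 6003779, lay within Camk2b, a calcium-dependent kinase gene, beside the start of an annotated transcript, with Ykt6 as the nearest gene start. The remaining 4 of the 10 peaks kept were intergenic 73.3 kb from Irf2bp2 (chromosome 8, 126666829 to 126667988), near an annotated start within Mtss1 (chromosome 15, 59055121 to 59057802), and in introns of the retinoid X receptor gene Rxra (chromosome 2, 27697962 to 27705425) and of Cxxc5 (chromosome 18, 35833835 to 35846885), with folds between 10.77 and 10.95.

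Joining replicated peaks across gaps of up to 5 kb gave 48463 domains. The largest spanned 117.9 kb over the start and first part of Zmiz1 (chromosome 14, 25450348 to 25568225), of which 77.8 kb was covered by 53 peaks. The next were at Mical2 (chromosome 7, 112202333 to 112320038, 76.0 kb covered), within Dab2ip (73.8 kb), within the transcription factor gene Nfib (70.3 kb), at Lrrfip1 (68.6 kb), over Casz1, a zinc finger gene required for heart development, and the adjacent Pex14 (65.5 kb), at Shb (64.7 kb), at Pitpnm2 (63.4 kb), over Gse1 with Gins2 as the nearest start site (60.9 kb), and at Abtb2 (60.8 kb). The covered bases of replicate 2's own list amounted to between 44.6% and 78.3% of those of the replicated list within the 100 largest domains, and 99 of the 100 reached 50% in both replicates. The covered bases did not have to be the same ones, and the replicated list was made with both replicates' lists. Over the whole genome replicate 2's list covered 42.7 Mb, against 79.0 Mb in the replicated list. The whole list thus also met the 50% mark, which does not set these domains apart. These 100 domains held 5.13% of all covered bases and the start sites of 55 protein-coding genes. Of 74 transcription factor, contractile and calcium handling genes, 2 had their start site in them, Tead1 and Ryr2. Random lists held a mean of 0.140 start sites for the transcription factor list, 0.0566 for the contractile list and 0.108 for the calcium handling list, so few could be expected, and the permutation test of start sites held, which made no call (adjusted p = 1.0 for each list), had little power. The number of such heart genes was between 0 and 6 under the alternatives.

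Away from start sites, 8 of 15 motifs passed the test as more frequent at the peaks than in matched sequence, among them those of MEF2, NKX2-5 and GATA factors and also those of CTCF, ETS and AP-1 factors. Windows of 400 bp around the summits of 100609 replicated peaks more than 2 kb from any TSS were compared with as many windows outside all peaks, matched on chromosome, GC and repeats, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 15 motifs. The motif of the MEF2 factors, which drive muscle genes, stood out: YTAWWWWTAR occurred in 7.78% of the peak windows and 3.97% of the matched windows, an odds ratio of 2.04 (95% interval 1.964 to 2.124). The odds ratio was 1.89 in replicate 1's list and 1.99 in replicate 2's. NKX2-5 had an odds ratio of 1.31 (1.21 to 1.42), GATA, as WGATAR, 1.28 (1.25 to 1.30) with 56.0% against 49.9% of windows, CTCF 1.26 (1.09 to 1.46), TEAD 1.23 (1.199 to 1.256), ETS 1.22 (1.14 to 1.30), AP-1 1.14 (1.103 to 1.177) and SRF 1.08 (1.01 to 1.14, adjusted Fisher's exact p = 0.0309). HAND/E-box was lower, at 0.950 (0.933 to 0.968). No call was made for T-box (0.955, adjusted Fisher's exact p = 0.233), SOX (1.02, 0.258) and, among the controls, for the liver factor HNF4 (1.07, 0.298) or for RFX, POU5F1-SOX2 and REST, each found in at most 12 windows of either kind. T-box was nonetheless called lower under 7 of 9 alternatives, including each replicate's own list (0.923 and 0.893), with adjusted Fisher's exact p values from 3.03e-07 to 0.538 over all of them. SOX was called higher in replicate 1's list (1.03) and against flanks matched on GC and repeats (1.088), and lower against unmatched flanks (0.942), over a range from 3.45e-05 to 0.802, and HNF4 higher against unmatched flanks (1.15). The CTCF call was lost in replicate 2's list (1.04, against 1.66 in replicate 1's) and the ETS call in the stronger part of the peaks (1.08), with adjusted Fisher's exact p values of up to 0.833 and 0.162 over their alternatives. Against windows 5 kb either side of the peaks, which had a mean GC of 44.3% against 47.3% at the peaks, the MEF2 odds ratio was 1.11, whereas with those flanks matched on GC and repeats it was 1.97 and that of GATA 1.34. The CTCF result turned with the window, at 0.469 for 200 bp windows, and to 0.945 with the replicated peaks that touched both replicates' own peaks. HAND/E-box was 1.101 against the unmatched flanks, and its call was lost against the matched flanks (1.001) and in 200 bp windows (0.978). Scrambled orders of the MEF2, GATA, TEAD and NKX2-5 consensuses gave odds ratios from 0.731 to 1.198 against the same matched windows. The odds ratios of AP-1, SRF, HAND/E-box and T-box lay inside that range. Those motifs, ETS and CTCF were not scrambled, so their calls cannot be taken as particular to the motif.

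**Figure D4:**
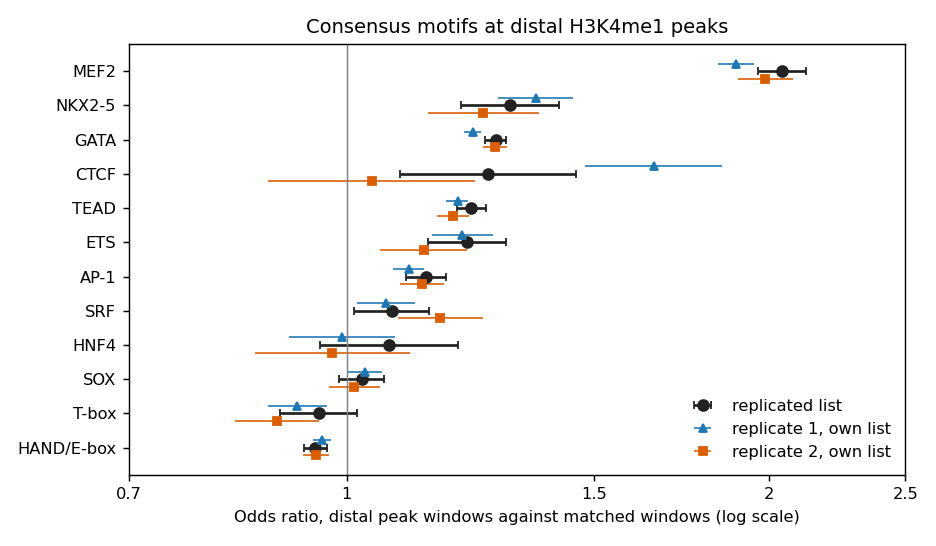
Odds ratio of holding each consensus motif, for 400 bp windows at distal peaks against windows matched on chromosome, GC and repeats (horizontal log axis), for the 12 motifs found in at least 100 windows. Black circles are the replicated list, blue triangles replicate 1 and orange squares replicate 2, with 95% intervals as bars. MEF2 lies apart from the other motifs at 2.04, and HAND/E-box below 1 at 0.950.

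Few peaks were called on the X chromosome, and the amount of the mark there outside called peaks was not measured. Peaks of the replicated list covered 0.241% of the X and 3.28% of the autosomes, a ratio of 0.0734, with a mean over the replicates' own lists of 0.0950 ± 0.0477 (SD, n = 2; 0.129 in replicate 1 and 0.0613 in replicate 2). The X made up 6.17% of the assembled length and held 1099 peaks, or 0.779% of the list. The autosomes ranged from 2.40% on chromosome 3 to 5.07% on chromosome 11, so the X fell below every autosome in both replicates by far more than the replicates' spread. No list held a peak on the Y chromosome. The ratio depended on the setting, at 0.115 by the number of peaks per Mb and 0.0472 in the stronger part of the peaks.

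**Figure D5:**
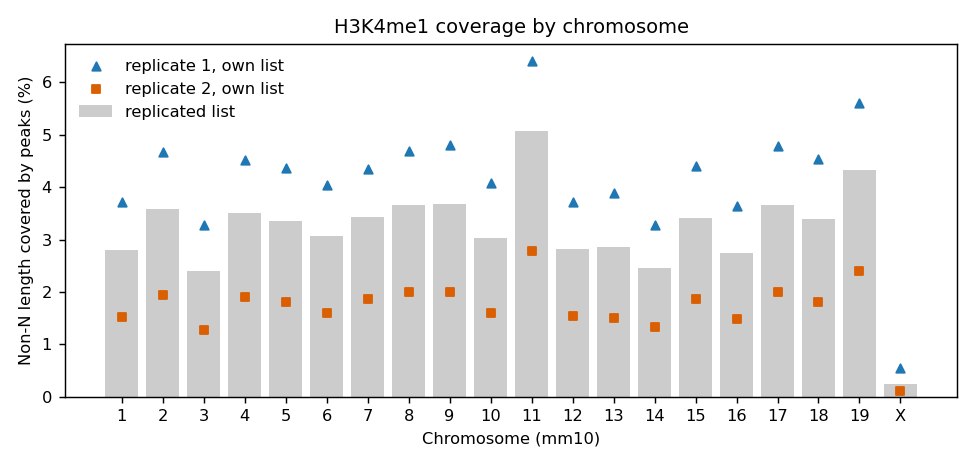
Percent of the assembled length of the mm10 autosomes and the X covered by H3K4me1 peaks (vertical axis). Grey bars are the replicated list, blue triangles replicate 1 and orange squares replicate 2. Of these, chromosome 11 was the most covered at 5.07% and the X the least at 0.241% in the replicated list. The Y, which held no peak, is not drawn.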

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

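Over all results, 330 of 420 recomputed values kept their direction and side of the threshold or moved by less than the spread, and 38 changed direction, 33 of them without a call before or after. The alternatives with peaks touched by both replicates' own peaks and with flanks matched on GC were chosen after seeing the data. Where values moved, the cause was not tested unless it is stated. No paired analysis was possible because the series has 1 group.

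The overlap of replicate 1's peaks was 38.5% at 1 bp, 18.4% with 50% of both peaks, 12.7% with a −log10 q of at least 2 and 38.0% with equal numbers of peaks, and that of replicate 2's peaks 90.2%, 37.5%, 92.7% and 68.8%. Deposited intervals did not overlap within a list, so merging them changed nothing. The promoter share was 9.90% at 500 bp, 32.1% at 2500 bp, 22.4% by any overlap, 20.4% in the stronger part of the peaks and 16.6% to 18.5% in each replicate's list alone; the first 3 follow from the width counted. The CpG-poor ratio was 0.875 at a CpG ratio of 0.5. The X ratio was 0.0613 to 0.129 in each replicate's list alone, 0.115 by number of peaks per Mb and 0.0472 in the stronger part.

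Of the gene lists, metabolism lost its call without replicate 1 (ratio 2.499, and 2.67 without replicate 2) and at ± 100 kb (2.00). Endothelium gained one without replicate 2 (2.17, and 2.05 without replicate 1), at ± 20 kb (2.35), over the gene body (3.05) and by number of peaks (2.08). Housekeeping lost it with peaks touched by both replicates (2.20) and with CpG class matched (1.62). The transcription factor, contractile, calcium handling and signalling lists passed under all 12 alternatives.

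Gene lists without a call changed sides of 1 as follows, still without a call. With CpG class matched the ratio rose to 1.094 for epicardium, 1.157 for erythroid, 1.37 for macrophage, 1.842 for hepatocyte, 1.625 for skeletal muscle and 1.011 for germline genes. At ± 20 kb it rose to 1.252 for epicardium, 1.098 for neural and 1.572 for skeletal muscle genes, and by number of peaks to 1.154, 1.167 and 1.062. At ± 100 kb it was 0.967 for fibroblast, 1.074 for skeletal muscle and 1.44 for lung genes, and with unmatched random lists 0.796 for fibroblast and 1.038 for skeletal muscle genes. Over the gene body it was 1.367 for neural genes. In the stronger part of the peaks it was 1.001 for hepatocyte and 1.09 for skeletal muscle genes, and with the stricter q 1.035 for skeletal muscle. In each replicate's list alone it was 0.731 to 1.024 for skeletal muscle and 0.862 to 1.005 for lung genes.

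The HAND/E-box odds ratio turned to 1.101 against unmatched flanks and 1.001 against matched flanks, that of SOX to 0.942 against unmatched flanks, and that of CTCF to 0.945 with peaks touched by both replicates and 0.469 in 200 bp windows. Without a call, T-box turned to 1.032 against unmatched flanks, HNF4 to 0.914 with peaks touched by both replicates, 0.974 in the stronger part and 0.977 to 0.992 in each replicate's list alone, and RFX to 1.769 in the pooled list, 1.222 in 200 bp windows, 1.858 against unmatched and 1.154 against matched flanks, and 1 to 1.56 in each replicate's list alone. MEF2, GATA, TEAD, NKX2-5 and AP-1 stayed higher under all 9. The share of the 100 largest domains in which the covered bases of each replicate's own list came to at least 50% of those of the list used was 92% in the pooled list and 100% with peaks touched by both replicates, with the stricter q and in the stronger part. Heart gene starts in them numbered 1 in each replicate's list alone, with peaks touched by both and in the stronger part, 0 with the stricter q, 6 at gaps of 12 kb and 0 at 1 kb. Without read depth, whether a peak missing from replicate 2 is absent or undetected cannot be settled.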

Other observations

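The test of the X copy number and the lowering of every fold were chosen only after the result was seen, as were the receptor families, and the scrambled motifs only after the odds ratios were. Of the protein-coding genes, 19.4% had no replicated peak within 50 kb of their start site. Among 1135 olfactory receptor genes the share was 83.6%, and among 329 vomeronasal receptor genes 92.1%. These families are used by sensory neurons of the nose, and they lie in clusters, so their windows overlap and are not independent.

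The X chromosome was covered at 0.0734 of the autosomal level. Its number of protein-coding start sites, its GC and its repeats, as matched here, could account for a part but not for all of this. Start sites were matched only by a coarse count, and the kind of genes and their expression were not matched. Autosomal 100 kb bins matched on start site number, GC and repeats were covered at 1.005%, against 3.28% of all autosomes and 0.250% of the X bins. The ratio of the X to the matched bins was 0.249 (0.208 to 0.293 over resampled bins). In the replicates' own lists it was 0.399 (0.356 to 0.442) and 0.211 (0.1765 to 0.245), replicate 1 first, so the size of the remaining deficit depended on the list. Nor was the deficit confined to distal sites: the share of CpG-rich start sites with a peak within 3 kb was 44.9% on the X and 93.3% on the autosomes, a difference of −48.4 percentage points (−54.4 to −42.3). Fewer X copies in the mixed-sex pools stay open. The 100th strongest X peak had 0.699 (0.671 to 0.711) of the fold enrichment at the same rank in matched bins, and the 500th 0.705 (0.683 to 0.741). A ratio under 0.5 would have excluded fewer copies as the only cause, but that bound is for a pool of males only, so the test could hardly exclude them. The X held 0.329 of the matched number of peaks. Fewer peaks from any cause lower the fold at a fixed rank, so these ratios do not measure the copy number. Both intervals lay below the 0.75 of equal numbers of both sexes, which for the same reason decides nothing about copies. The sex ratio of the pools was not given. A loss of weak peaks first cannot be told apart from fewer X copies. The X held 0.0378 (0.0133 to 0.0691) of the matched number of peaks among the strongest 10%. The bound of 0.5 set for that test was wrong, because lowering every fold to 0.75, as with equal numbers of both sexes, would already leave 0.0983. The measured interval lay below 0.0983. Lowering every fold to the measured 0.699 would leave 0.0456, inside the interval, but that factor came from the same peaks. Silencing of an X copy in females, a background that corrects for copy number, and mapping were not tested.

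Replicate 1 had 228627 peaks and replicate 2 112269. Noise placed at random is not the whole of the excess, since the replicate 1 peaks that shared no base with replicate 2 lay at promoters at 2.43 times the genome's share, against 3.24 for the shared peaks. Noise as a part of it stays open, and the median fold of these peaks was 3.35, against 4.41 for the shared peaks. Of these peaks 38.0% were in the replicated list, against 98.3% of the shared peaks. That contrast cannot decide about noise, because the replicated list was itself made with both replicates' lists. Fewer usable reads in replicate 2 stay open and were not tested, because no read counts were given and each list's scores are its own. The lists also differed in the number of input files, which was not tested, and no biological difference between the pools was tested.

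The MEF2 and GATA motifs were more frequent at distal peaks than in matched sequence. Base composition alone would give scrambled orders of the same consensus the same excess, but the highest odds ratio of 20 scrambled orders was 1.187 for MEF2, against 2.04 (1.964 to 2.124), and 1.198 for GATA, against 1.28 (1.25 to 1.30). The highest scrambled value was 1.059 for TEAD, against 1.23 (1.199 to 1.256), and 1.03 for NKX2-5, against 1.31 (1.21 to 1.42). Repeats that carry the motif beyond the matching stay open. Binding was not measured, so no biological explanation was tested.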
